A study of Arabidopsis thaliana with 18 samples.

How the data were processed

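RNA from whole seedlings of 5 Arabidopsis lines was hybridised to 18 single-colour arrays with biotin label. Per the labels' protocols, each line was split into 3 flasks, 3 additional flasks of the PLT4 line were prepared as mock, and harvests were kept within a short interval so that the hour of day differed little, with genotypes induced 5 min apart. The labels list 4 mock libraries, so the origin of 1 of them is not given in the sources used here. A separate experiment on a 35S-driven PLT2 fusion is mentioned per the labels' protocols and is not analysed here. All samples were grouped by their titles.

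The deposited table holds log2 values with 1 column per array. Per the submitters' processing notes, RMA and limma 3.24.15 were used, with no role or order given. RMA corrects background, normalises arrays to a common distribution and summarises probes, so that differences near the background (log2 values of about 3 to 4) are compressed, and a change shared by most genes would be removed. The table has no detection calls and no build of a genome is named, so no coordinates are given. Of 21494 rows, 64 control rows were used only to look at RNA quality. The remaining 21430 probe sets are named by locus, of which 21231 matched a locus of the TAIR10.1 gene table, used for names only, and 199 did not. In 106 groups, 221 probe sets had identical values in all arrays and cannot be told apart by these values, and 21120 probe sets matched exactly 1 gene.

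All 18 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with 1 coefficient per group and no covariate, with moderated two-sided tests and Benjamini-Hochberg adjustment over 21430 probe sets for each contrast, at a threshold of 0.05. Contrasts were each line against mock, the mean of the 5 lines against mock, an F test among the 5 lines, their 10 pairs, and PLT1 and PLT4 against PLT5 and PLT7. This design, the 22 gene lists (290 genes, 260 measured) and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation as the alternative, adjusted over the lists of a contrast, and members were counted over all probe sets and adjusted over the list alone. The lists are the PLT/AIL family, auxin biosynthesis, auxin transport, auxin response, root stem cell niche, mitotic genes, G1/S and DNA replication, embryo regulators, seed storage, ribosome biogenesis, photosynthesis, xylem, root hair, endodermis and suberin, shoot meristem, cytokinin, gibberellin, growth-regulating factors, circadian clock, hypoxia, jasmonate and touch, and salicylate defence. The PLT/AIL family list, which holds the induced genes, had 3 of 8 higher and 2 lower in the mean of the 5 lines, also when adjusted over the list alone (adjusted p = 0.463).

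Named genes are the 8 PLT/AIL genes, the 10 called genes of largest rise and of largest fall for the mean and difference contrasts, the 8 of each for a single line, the 10 of smallest p in the F test, and up to 4 called members of each list. Each of the extremes against mock needed every dex library on the same side of all mock libraries, a probe set matching 1 gene and a symbol. Where fewer than 4 members of a list were called, up to 2 others were eligible with values only, and the induced gene was left out of the extremes of its line. The text names a part of these. CYCD3;3, WER, GPAT5, LEC1, CYP86A1 in PLT4 and the genes given as examples for all 5 lines fall outside the rule and were chosen after their values were seen.

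The fit was tested on simulated data with 200 probe sets changed by known amounts. For PLT4 against mock, 96% of 50 probe sets raised by 1 log2 unit and 72% of 50 raised by 0.5 were called, and 6.25% of calls were false. Among the simulated comparisons, recovery at 0.5 was lowest for PLT3 against mock (52%), and false calls were highest for PLT4 against PLT5 (8.72%). A simulated shift of the ribosome biogenesis list was ranked 1 of 22 by camera. Alternatives were each library left out, array weights, trend and robust variance, median centring, quantile normalisation, dim probe sets left out, probe sets matching 1 gene, fits on the compared groups or the dex arrays alone, a common adjustment over the 5 contrasts, a 2-fold minimum, and the replicate number as a block. The fit with 3 libraries with a PLT signal against their label left out was added after the data were seen. Comparisons that share the mock libraries were set beside 100 simulated sets of unchanged groups.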

Results

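Whole Arabidopsis thaliana seedlings of 5 transgenic lines were profiled on arrays. Each line expressed a PLETHORA (PLT) transcription factor fused to the glucocorticoid receptor domain (GR) from the constitutive 35S promoter, so that the steroid dexamethasone (dex) lets the fusion protein enter the nucleus. PLT proteins are AP2-domain factors that pattern and maintain the root meristem. PLT3, PLT4, PLT5 and PLT7 are also known as AIL6, BBM, AIL5 and AIL7. Seedlings 4 days old were moved to liquid medium, about 50 per flask, and on the next day received 10 µM dex for 6 h. The dex groups held 3 libraries each for PLT1, PLT4, PLT5 and PLT7 and 2 for PLT3. The mock group held 4 libraries of the PLT4 line treated with the solvent DMSO. The labels call the libraries of a group biological replicates. The 18 arrays gave log2 values with medians between 5.70 and 5.80, and their number limits the precision.

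The PLT4 line alone had both a mock and a dex group. Line and treatment therefore differed together in the 4 other comparisons, and no group received dex without a PLT fusion. All changes are log2 differences with their standard error (SE) from limma, and a gene is called, or said to rise or fall, at an adjusted p under 0.05 over 21430 probe sets. Gene lists were tested against all other genes with camera at a preset correlation between genes of 0.01.

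The PLT transcripts were read first, as a check of the labels. The PLT1 probe set stood at 11.00 and 11.08 in PLT1 replicates 1 and 2, but at 3.5 in the library labelled PLT1 replicate 3, where the 15 libraries of other groups lay between 3.52 and 3.92. That library instead had the PLT2 probe set at 10.28, against 3.67 to 6.07 in the 17 others. In the other lines the induced gene was high in every library. PLT3 averaged 10.91 ± 0.06 (SD, n = 2) in its line, PLT5 11.20 ± 0.07 (SD, n = 3) and PLT7 11.01 ± 0.11 (SD, n = 3). PLT4 was at 11.47 ± 0.08 (SD, n = 4) in mock and 10.76 ± 0.08 (SD, n = 3) in its dex group, a change of -0.72 ± 0.30 (adjusted p = 0.0767). It passed once the library labelled PLT1 replicate 3 was left out (-0.72 ± 0.08, adjusted p = 1.38e-06), and without PLT1 replicate 2 (adjusted p = 0.0399).

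Against mock, PLT3 rose by 6.20 ± 0.38 in its line, PLT5 by 4.84 ± 0.14 and PLT7 by 7.48 ± 0.09. PLT1 rose by 4.85 ± 1.18 with all 3 libraries of its group and by 7.36 ± 0.10 with replicates 1 and 2 alone. A further PLT2 signal of 6.07 was present in PLT5 replicate 3, whose group otherwise had 4.06 and 3.95. A PLT3 signal of 6.49 was present in PLT7 replicate 1, whose group otherwise had 4.63 and 4.39. Because mock carries the 35S-driven PLT4, the fall of PLT4 in the lines without it compares lines. PLT4 stood at 7.32 and 7.51 in PLT1 replicates 1 and 2, and averaged 6.70 ± 0.03 (SD, n = 3) in PLT7, 6.21 ± 0.14 (SD, n = 2) in PLT3 and 4.77 ± 0.13 (SD, n = 3) in PLT5. Without the library labelled PLT1 replicate 3, each pair of these 4 lines differed in PLT4, from PLT1 above PLT5 by 2.64 ± 0.10 (adjusted p = 1.7e-12) to PLT3 below PLT7 with -0.49 ± 0.10 (adjusted p = 0.00155). With it, PLT1 and PLT7 differed by 0.10 (adjusted p = 0.889, and -0.16 or -0.25 without PLT1 replicate 1 or 2), PLT1 and PLT3 by 0.59 (adjusted p = 0.305), and PLT3 and PLT5 by 1.44 (adjusted p = 0.122). In the mean of the 5 lines the family member ANT fell (-0.75 ± 0.12, adjusted p = 5.27e-05), and AIL1 was not called (0.12 ± 0.08, adjusted p = 0.242).

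**Figure D1:**
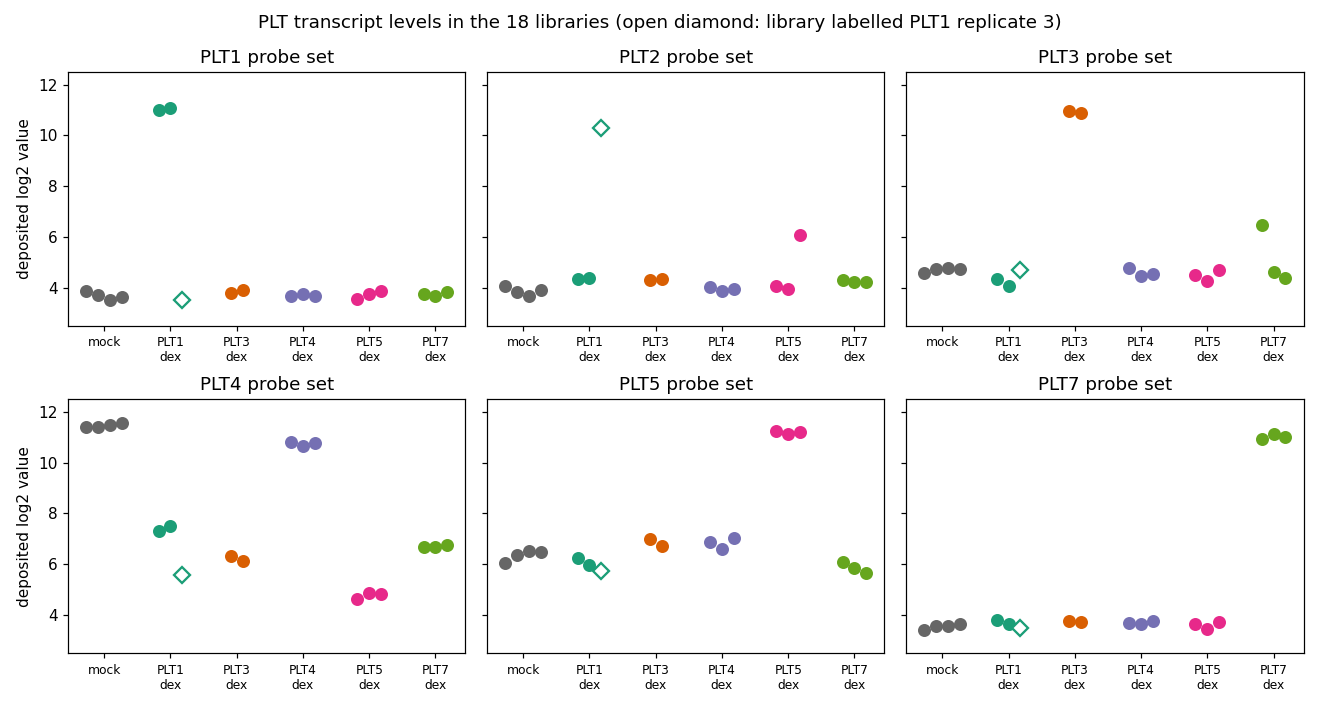
Deposited log2 value (vertical axis) of 6 PLT probe sets in each of the 18 libraries, grouped as mock or by induced line (horizontal axis), with 1 point per library and an open diamond for the library labelled PLT1 replicate 3. That library lies at 3.5 for PLT1 and 10.28 for PLT2, while PLT1 replicates 1 and 2 lie at 11.00 and 11.08 for PLT1.

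The library labelled PLT1 replicate 3 also stood apart from its group over all probe sets. Its mean correlation with replicates 1 and 2 was 0.968, while those 2 correlated at 0.994, and the other groups had pairs at 0.989 to 0.997. Its highest correlation was 0.979, with PLT4 replicate 3. The difference between the 3' and 5' probe sets of the actin control, which grows as RNA degrades, was 2.67 log2 units in it and 1.08 to 1.64 in the 17 others. The same difference was 1.79 for the ubiquitin control, against 1.19 to 1.44 in the others, but 1.28 for the GAPDH control, within the 1.13 to 1.53 of the others. It was kept where its label puts it, and each direction given for PLT1 rests in part on it, as do the shared spread and the mean of the 5 lines. For each contrast, the count of called probe sets without it is given beside that with it. Members of lists were counted with all libraries.

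The average response of the 5 lines was asked for first, as the mean of the 14 dex libraries by line against the 4 mock libraries. The auxin-synthesis gene YUC8, the cytokinin response factor CRF3 and genes of ribosome biogenesis rose, and genes of the endodermal barrier and the xylem wall fell. The largest rises belonged to CYP91A2, a cytochrome P450 (3.6 ± 0.16, 12.1-fold), the early light-induced ELIP2 (3.41 ± 0.16), the glutathione transferase ATGSTF13 (3.3 ± 0.25), CRF3 (3.1 ± 0.09, 8.59-fold) and YUC8, an auxin-synthesis monooxygenase (3.02 ± 0.10, 8.13-fold). The exchanger CHX16, the carboxypeptidase-like scpl35, the mechanosensitive channel MSL9, the ethylene-forming oxidase ACO1 and the small GTPase ROP9 rose by 2.87, 2.71, 2.7, 2.69 and 2.64. Apart from PLT4, the largest falls were those of GASA6, a gibberellin-regulated peptide (-3.37 ± 0.64), the arabinogalactan protein FLA9 (-2.74 ± 0.47), the bHLH factor BEE2 (-2.71 ± 0.32), BZIP61 (-2.68 ± 0.28) and the aquaporin PIP2A (-2.67 ± 0.33). SQE6, the wall enzyme XTH17 and the glucosinolate enzymes AOP2 and IGMT1 followed with -2.67, -2.63, -2.56 and -2.43. Adjusted p of these genes ran from 8.52e-13 for CRF3 to 0.00035 for GASA6. That every dex library lay on the same side of all mock libraries was a condition for naming them, not a result. In total, 9736 probe sets were called, 4922 higher and 4814 lower, and 1227 of them changed at least 2-fold, 465 higher and 762 lower. Without the library labelled PLT1 replicate 3 there were 10735 calls.

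Of the ribosome biogenesis genes, all 9 of 9 measured members were higher, with the same number when adjusted over the list alone, among them the fibrillarin FIB2 (1.13 ± 0.07) and the small nucleolar RNP proteins NAP57 (1.00 ± 0.06) and NOP56 (0.86 ± 0.08). The list's adjusted p was 4.15e-07, and the adjusted p was 0.161 with an estimated correlation. Of the genes of G1/S and DNA replication, 11 of 16 rose and 1 fell, and 12 and 1 when adjusted over the list alone (adjusted p = 7.15e-05, or adjusted p = 0.324 with an estimated correlation). Examples were the ribonucleotide reductase subunit RNR2A (1.61 ± 0.07) and the helicase subunits PRL (0.95 ± 0.08) and MCM3 (0.94 ± 0.09), while the cyclin CYCD3;3 fell (-0.20 ± 0.07). Of the mitotic genes 11 of 14 rose, and 12 when adjusted over the list alone (adjusted p = 0.000603, or adjusted p = 0.354 with an estimated correlation). They included the cyclins CYCB1;3 (0.83 ± 0.11) and CYCB1;1 (0.78 ± 0.12) and the spindle protein PLE (0.75 ± 0.12).

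Of the endodermis and suberin list 13 of 14 members were lower, and 13 when adjusted over the list alone. CASP1, a scaffold protein of the Casparian strip, fell by 2.34 ± 0.21, ESB1 by 1.76 ± 0.17, and the suberin enzymes FAR1 and CYP86A1 by 1.60 ± 0.23 and 1.59 ± 0.29. CYP86A1 was not called in PLT4, the only line with its own mock (0.07, adjusted p = 0.917), so its fall rests on comparisons between lines. The list's adjusted p was 6.53e-07, and the adjusted p was 0.0999 with an estimated correlation, or 0.00426 without the library labelled PLT1 replicate 3. Of the xylem and secondary wall list 8 of 10 fell, also when adjusted over the list alone, led by the cellulose synthase CESA4 (-1.21 ± 0.15) and the laccase LAC4 (-1.09 ± 0.16), with adjusted p = 0.000522, or adjusted p = 0.161 with an estimated correlation. In the root hair and epidermis list 6 of 10 fell and 1 rose, also when adjusted over the list alone, and the list was not called (adjusted p = 0.0806). PRP3, a root hair wall protein, fell (-1.30 ± 0.12), and WER, a factor of the hairless cell fate, rose (0.46 ± 0.08).

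Auxin genes moved in both directions, and none of the 3 auxin lists was called. In auxin biosynthesis 3 of 14 rose and 4 fell, and 4 and 4 when adjusted over the list alone (adjusted p = 0.463). Beside YUC8 these were YUC3 (1.80 ± 0.22) and TAA1 (0.67 ± 0.06, not called in PLT1 alone once the library labelled PLT1 replicate 3 was left out, adjusted p = 0.078), with TAR2 lower (-0.31 ± 0.09), which was not called without mock replicate 2 or 3 (adjusted p = 0.0544 and 0.0576). Once dim probe sets (mean value below the median of all) were left out, this list was called higher (adjusted p = 0.00905). In auxin transport 4 of 16 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.463): the efflux carrier PIN4 (0.96 ± 0.11) and the influx carrier LAX2 (1.60 ± 0.08) rose, and LAX3 fell (-1.07 ± 0.11). In auxin response 4 of 18 rose and 7 fell, and 5 and 7 when adjusted over the list alone (adjusted p = 0.406), with IAA30 higher (1.58 ± 0.16) and GH3.5 lower (-0.93 ± 0.09).

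Among meristem and organ regulators, 7 of 16 measured genes of the root stem cell niche rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.307). RGF3, which encodes a root meristem growth factor peptide, rose by 2.34 ± 0.20, and SCR and SHR, which specify the ground tissue, by 0.81 ± 0.10 and 0.73 ± 0.11. This list too was called higher with dim probe sets left out (adjusted p = 0.0218). The growth-regulating factor list had 3 of 8 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.211), led by the coactivator GIF1 (2.36 ± 0.09, 5.15-fold) and GRF2 (0.89 ± 0.13). Of the shoot meristem and boundary list 2 of 14 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.705), the boundary factor CUC2 by 1.11 ± 0.13 and AS1 by -0.98 ± 0.12. Of the embryo regulators 1 of 9 was called, also when adjusted over the list alone (adjusted p of the list = 0.956). It was AGL15 (0.35 ± 0.11), which was not called without mock replicate 4 (adjusted p = 0.062), and LEC2 was at -0.12 ± 0.06 (adjusted p = 0.111, or 0.0116 without mock replicate 3). Of the seed storage list 3 of 7 fell, also when adjusted over the list alone (adjusted p = 0.153, or 0.0173 without mock replicate 3), with the cruciferin CRA1 at -1.44 ± 0.40.

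Hormone and environment lists were mixed. Of the cytokinin list 9 of 18 fell, also when adjusted over the list alone, including the response regulators ARR6 (-0.92 ± 0.15) and ARR7 (-0.90 ± 0.08) and the synthesis gene IPT3 (-0.81 ± 0.10). Its adjusted p was 0.00737, and the adjusted p was 0.33 with an estimated correlation and 0.0526 with dim probe sets left out. Of the jasmonate, touch and wounding list 6 of 9 fell, also when adjusted over the list alone (adjusted p = 0.0028, or adjusted p = 0.0985 with an estimated correlation). The members that fell most were the touch genes TCH4 (-1.81 ± 0.18), TCH3 (-1.22 ± 0.09) and TCH2 (-1.03 ± 0.09) and the lipoxygenase LOX2 (-1.31 ± 0.40, not called without mock replicate 4, adjusted p = 0.0867). Of the photosynthesis list 8 of 13 fell, also when adjusted over the list alone (adjusted p = 0.0028, or adjusted p = 0.354 with an estimated correlation), by small amounts such as -0.51 ± 0.07 for GAPB and -0.30 ± 0.05 for RCA. The gibberellin list had 2 of 9 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.463). The synthesis gene GA20OX2 rose (1.13 ± 0.23) while GA3OX1 fell (-0.90 ± 0.11). The hypoxia list had 2 of 10 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.861), with the hemoglobin HB1 at -1.13 ± 0.18. Of the salicylate defence list 1 of 8 fell, also when adjusted over the list alone (adjusted p = 0.576), namely PAD4 (-0.46 ± 0.09).

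The circadian clock list, which moves with the hour of harvest, was not called (adjusted p = 0.463), with 3 of 10 higher and 1 lower, also when adjusted over the list alone. It holds morning and evening genes, which a shift of the hour can move in opposite directions. The list test looks for 1 direction, so it cannot show that the hours of harvest were alike. Single clock genes nonetheless moved with the groups. CCA1, a morning factor, fell in each line, from -1.17 in PLT3 to -2.56 in PLT7, and its SD among the 4 mock libraries was 0.781. GRP7 rose in each line, from 0.69 in PLT3 to 1.81 in PLT7, and the evening gene PRR5 rose in PLT1, PLT4 and PLT7 by 1.12, 1.51 and 2.14. The call of CCA1 in PLT3 ended with only the compared groups (adjusted p = 0.0686), with a trend and robust variance (0.0663) and without 1 of many libraries, among them PLT3 replicate 1 or 2 (0.225 and 0.12), and in PLT5 without PLT5 replicate 1 or 3 (0.0502 and 0.0674). With only the compared groups GRP7 in PLT3 and PRR5 in PLT1 were not called (0.0578 and 0.0713), nor was GRP7 without PLT3 replicate 1 (0.179) or PRR5 without the library labelled PLT1 replicate 3 (0.70, 0.0562). A change in the mean need not hold in each line, and the library labelled PLT1 replicate 3 decides many of the calls in single lines. With it and without it, AGL15 was not called in PLT3, PLT4 and PLT5, CYCD3;3 in any line but PLT7, LOX2 in PLT4 and PLT5, TAR2 in PLT3 and PLT7, CRA1 in PLT5 and PLT7, FAR1 in PLT3 and PLT5, GA20OX2 in PLT5, HB1 in PLT3, PAD4, RCA and WER in PLT7, and CYP86A1 in PLT4. Not called with all libraries but called without that one, at adjusted p from 2.31e-08 for GASA6 to 0.0498 for GH3.5, were GASA6, BEE2, PIP2A, ANT, GA3OX1, IAA30, LAC4, PLE, RGF3, SHR, TAR2 and HB1 in PLT5, FLA9 in PLT3 and PLT5, YUC3 in PLT3, PLT4 and PLT5, GA20OX2 in PLT3 and PLT4, LOX2 in PLT1 and PLT3, PIN4 in PLT3, PAD4 and GH3.5 in PLT4, CRA1 in PLT1 and AGL15 in PLT7. The reverse held in PLT1 for TAA1 and WER, which were not called without it (adjusted p = 0.078 and 0.0557). Of the lists, 8 were called in the mean of the 5 lines with the preset correlation, and none with an estimated correlation on all libraries.

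**Figure D2:**
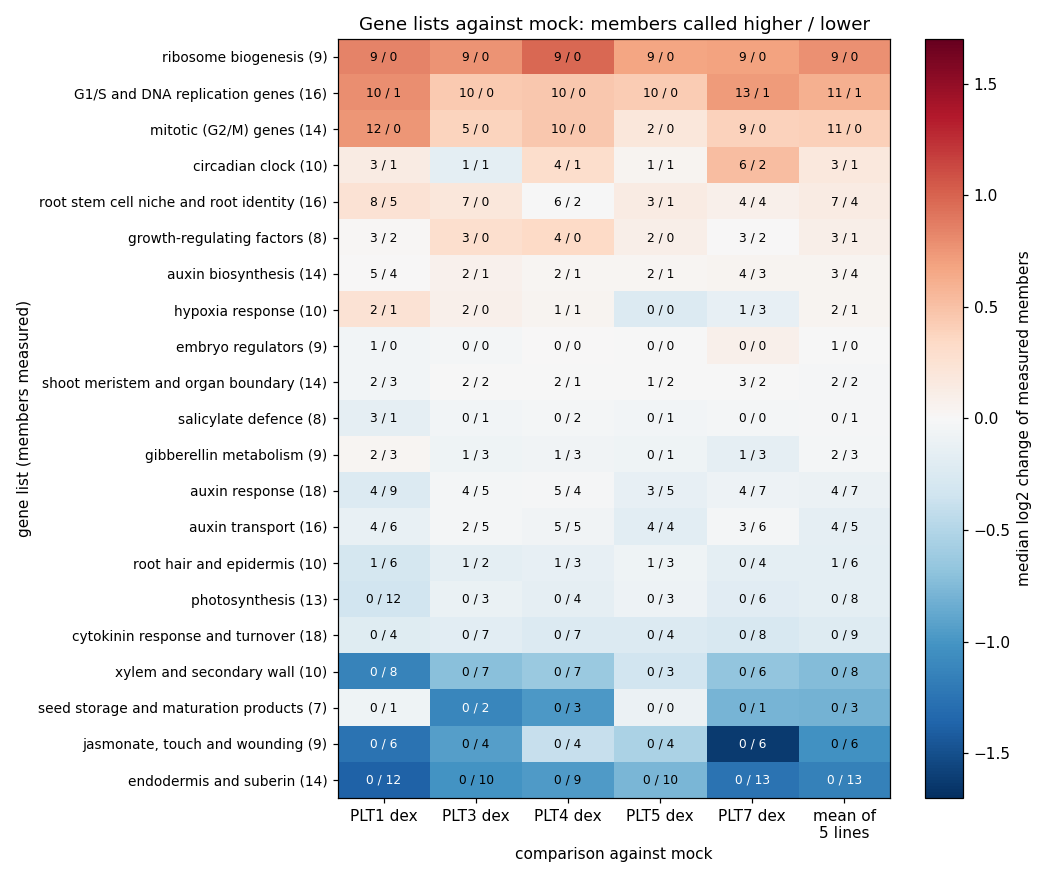
Gene lists (vertical axis, with the number of measured members) by comparison against mock (horizontal axis). Colour gives the median log2 change of the measured members, and each cell holds the members called higher and lower. All 9 ribosome biogenesis members were higher in each line, and 9 to 13 of 14 endodermis and suberin members were lower.

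PLT1 induction called 10361 probe sets in 3 libraries against 4, 5443 higher and 4918 lower. Without the library labelled PLT1 replicate 3 there were 10883, of which 9507 were called the same way in both. The gene changes that follow include that library. The actin-depolymerising factor ADF9 rose by 5.68 ± 0.19 (adjusted p = 7.02e-12), ATGSTF13 by 5.44 ± 0.34, RGF3 by 5.15 ± 0.27, MEE3 by 4.90 ± 0.23 and the auxin-synthesis gene YUC3 by 4.84 ± 0.30. GASA6 fell by 5.25 ± 0.86, AOP2 by 5.12 ± 0.24, FLA9 by 4.63 ± 0.64 and BZIP61 by 4.12 ± 0.37. The mitotic list reached 12 of 14 higher, and 12 when adjusted over the list alone (adjusted p = 0.000228, or adjusted p = 0.404 with an estimated correlation). Of the photosynthesis genes 12 of 13 fell, also when adjusted over the list alone (adjusted p = 0.000209, or adjusted p = 0.289 with an estimated correlation). Of the root hair genes 6 of 10 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0175, or adjusted p = 0.0913 with an estimated correlation). The endodermis and suberin list fell in 12 of 14 members, also when adjusted over the list alone (adjusted p = 1.33e-06). Its adjusted p was 0.0913 with an estimated correlation, and 0.00367 without the doubted library. The cytokinin list, 4 of 18 lower and also when adjusted over the list alone (adjusted p = 0.0383), lost its call with an estimated correlation (adjusted p = 0.426) and without that library (adjusted p = 0.101), without mock replicate 1 or 4 (0.0525 and 0.0681), with quantile normalisation (0.0803) and with dim probe sets left out (0.283).

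PLT3 induction, in 2 libraries against 4, called 5476 probe sets, 2771 higher and 2705 lower, and 6779 without the library labelled PLT1 replicate 3. ATGSTF13 rose by 4.55 ± 0.38, the GDSL lipase gene GLIP7 by 3.72 ± 0.17 (adjusted p = 1.01e-09), ELIP2 by 3.51 ± 0.25 and ACO1 by 3.33 ± 0.29. SQE6 fell by 3.08 ± 0.28, CRA1 by 2.81 ± 0.60, PSK4, a phytosulfokine precursor, by 2.74 ± 0.37, and IGMT1 by 2.62 ± 0.19. Of the root stem cell niche genes 7 of 16 rose, also when adjusted over the list alone (adjusted p = 0.0318, or adjusted p = 0.462 with an estimated correlation), among them RGF3 (2.03 ± 0.31) and SCR (1.09 ± 0.14). This list was not called without mock replicate 3 (adjusted p = 0.0568) or PLT3 replicate 1 (0.0968). Of the growth-regulating factors 3 of 8 rose, also when adjusted over the list alone (adjusted p = 0.0223, or adjusted p = 0.0854 with an estimated correlation, and 0.0558 without PLT3 replicate 2). The seed storage list had 2 of 7 lower, also when adjusted over the list alone (adjusted p = 0.0455). Its adjusted p was 0.545 with an estimated correlation and 0.0507 with quantile normalisation, and between 0.0539 and 0.138 without 1 of mock replicates 1 and 4, PLT1 replicate 2, the library labelled PLT1 replicate 3 and PLT3 replicate 1. The gibberellin synthesis gene GA20OX1 rose by 1.45 ± 0.16. Without PLT3 replicate 1 the count was 3212, where the remaining library is assumed to vary like the other groups.

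PLT4 induction is the comparison within 1 line, 3 dex against 4 mock libraries. It called 7224 probe sets, 3758 higher and 3466 lower, and 8468 without the library labelled PLT1 replicate 3. ADF9 rose by 4.11 ± 0.19, CRF3 by 3.68 ± 0.12 (adjusted p = 8.98e-12), CHX16 by 3.39 ± 0.18, GLIP7 by 3.25 ± 0.15 and YUC8 by 3.16 ± 0.13. GASA6 fell by 2.81 ± 0.86 (adjusted p = 0.018, not called without PLT4 replicate 2 or 3, 0.0536 and 0.0524), XTH6 by 2.7 ± 0.22, PIP2A by 2.65 ± 0.45 and the nitrate transporter NRT1.5 by 2.49 ± 0.50. All 9 of 9 ribosome biogenesis genes rose, also when adjusted over the list alone (adjusted p = 1.48e-09, or adjusted p = 0.135 with an estimated correlation). Of the endodermis and suberin list 9 of 14 fell, also when adjusted over the list alone (adjusted p = 0.000213). Its adjusted p was 0.169 with an estimated correlation and 0.0296 without the library labelled PLT1 replicate 3. CASP1 fell by 2.18 ± 0.29, while the suberin enzymes CYP86A1 and GPAT5 were at 0.07 ± 0.39 (adjusted p = 0.917, and -0.08 or -0.07 without mock replicate 4 or PLT4 replicate 1) and -0.19 ± 0.13 (adjusted p = 0.298). Of the growth-regulating factors 4 of 8 rose, also when adjusted over the list alone (adjusted p = 0.0206, or adjusted p = 0.135 with an estimated correlation, and 0.104 with dim probe sets left out). Of the seed storage list 3 of 7 fell, and 4 when adjusted over the list alone (adjusted p = 0.0249, or adjusted p = 0.456 with an estimated correlation, and 0.0527 and 0.0695 without mock replicate 1 or 4). No embryo regulator of 9 was called after induction of PLT4, and LEC1 was at 0.04 ± 0.10 (adjusted p = 0.817, and -0.03 or -0.01 without mock replicate 3 or PLT4 replicate 2). This does not show that they were unchanged. Small changes are compressed near background, where AGL15, for example, lay in mock (3.47 to 3.74).

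PLT5 induction called 4904 probe sets in 3 libraries against 4, 2418 higher and 2486 lower, and 6283 without the library labelled PLT1 replicate 3. CYP91A2 rose by 2.98 ± 0.21, ELIP2 by 2.78 ± 0.22, ACO1 by 2.76 ± 0.25 and MSL9 by 2.68 ± 0.12 (adjusted p = 1.05e-09). Apart from PLT4, the glucosyltransferase gene UGT75B1 fell by 1.90 ± 0.30, the heat shock gene HSP17.4 by 1.88 ± 0.52 (not called without PLT5 replicate 2 or 3, adjusted p = 0.0547 and 0.0657), NIC3 by 1.75 ± 0.20 and the ferritin FER1 by 1.65 ± 0.43. All 9 of 9 ribosome biogenesis genes rose, also when adjusted over the list alone (adjusted p = 5.9e-10, or adjusted p = 0.0917 with an estimated correlation). Of the endodermis and suberin list 10 of 14 fell, and 11 when adjusted over the list alone (adjusted p = 2.72e-06). The adjusted p was 0.0917 with an estimated correlation and 0.00577 without the library labelled PLT1 replicate 3. Of the mitotic genes 2 of 14 rose, also when adjusted over the list alone (adjusted p = 0.0168, or adjusted p = 0.614 with an estimated correlation, 0.0919 with dim probe sets left out and 0.0531 without mock replicate 1). Without PLT5 replicate 1 the count of calls was 3274.

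PLT7 induction called 9265 probe sets in 3 libraries against 4, 4860 higher and 4405 lower, and 10189 without the library labelled PLT1 replicate 3. ADF9 rose by 4.55 ± 0.19, MEE3 by 4.15 ± 0.23, CYP91A2 by 3.83 ± 0.21 and ROP9 by 3.77 ± 0.24 (adjusted p = 6.93e-09). BZIP61 fell by 4.02 ± 0.37, BEE2 by 3.91 ± 0.43, FLA9 by 3.85 ± 0.64 and the xylosidase BXL1 by 3.61 ± 0.61. Of the G1/S and replication genes 13 of 16 rose and 1 fell, also when adjusted over the list alone (adjusted p = 4.1e-05, or adjusted p = 0.297 with an estimated correlation). Of the endodermis and suberin list 13 of 14 fell, also when adjusted over the list alone, with FAR1 at -3.5 ± 0.31 (adjusted p = 3.15e-07). The adjusted p of that list was 0.0767 with an estimated correlation and 0.00331 without the library labelled PLT1 replicate 3. Of the jasmonate, touch and wounding list 6 of 9 fell, also when adjusted over the list alone. Its adjusted p was 0.000669, and the adjusted p of 0.0391 with an estimated correlation also passed, with TCH4 at -2.96 ± 0.24 and the jasmonate-synthesis gene AOS at -2.02 ± 0.13. Of the root hair list 4 of 10 fell, also when adjusted over the list alone (adjusted p = 0.0221, or adjusted p = 0.143 with an estimated correlation).

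**Figure D3:**
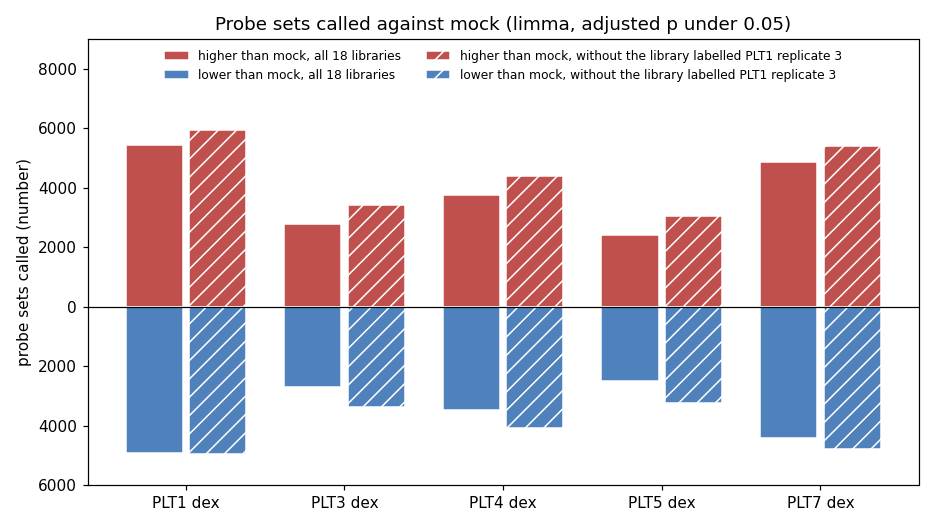
Number of probe sets called against mock (vertical axis, higher above 0 and lower below 0) for each induced line (horizontal axis), with all 18 libraries (plain bars) and without the library labelled PLT1 replicate 3 (hatched bars). PLT1 and PLT7 had 10361 and 9265 calls with all libraries, and PLT5 had 4904.

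The overlap of the lines was then counted. The same direction was called in all 5 lines for 3445 probe sets, 1866 higher and 1579 lower, and for 4325 without the library labelled PLT1 replicate 3. Among these were YUC8, LAX2, GIF1, CUC2 and all 9 ribosome biogenesis genes on the rising side, and CASP1, CASP2, CASP5, ESB1, CESA4, XCP2, TCH2, TCH3, TCH4 and ARR6 on the falling side. Of these, TCH3 lost its call in PLT4 without PLT4 replicate 3 (adjusted p = 0.143) among others, and ARR6, CESA4 and XCP2 theirs in PLT5 without PLT5 replicate 1 (0.169, 0.0575 and 0.0541). Lists that were independent would share 5.55, and simulated unchanged groups against the same mock libraries shared 0 on average. Unchanged groups yield few calls at all, so this 0 cannot show how much of the overlap the shared mock libraries add. All 5 lines also share the dex treatment, so an overlap above 5.55 need not be a response to PLT. With only 2 of the 4 mock libraries, over 6 choices and without the doubted library, the count was 3769 to 4243. At least 1 line called 12606 probe sets, and 3313 were called in exactly 1 line, which is no test of a difference between lines. In opposite ways in 2 lines 208 were called, and 401 without the library labelled PLT1 replicate 3. Those that also differed between the 2 lines numbered from 0 for PLT3 and PLT5 to 70 for PLT4 and PLT7, and without that library from 6 for PLT4 and PLT5 to 150 for PLT1 and PLT4. The changes correlated across probe sets, which are not independent replicates, from 0.774 for PLT1 and PLT5 to 0.902 for PLT1 and PLT7 without that library. Simulated unchanged lines gave 0.377 to 0.429, and separate sets of 2 mock libraries gave means of 0.717 to 0.869. The covariance of the changes was 0.149 for PLT3 and PLT5, the lowest, and 0.445 for PLT1 and PLT7, the highest, where the simulated covariance was 0.00554 and 0.00555. PLT1 and PLT7 shared 4462 higher and 3888 lower calls, against 1499 and 1103 for independent lists. The observed covariances and these shared calls, too, are without the library labelled PLT1 replicate 3.

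**Figure D4:**
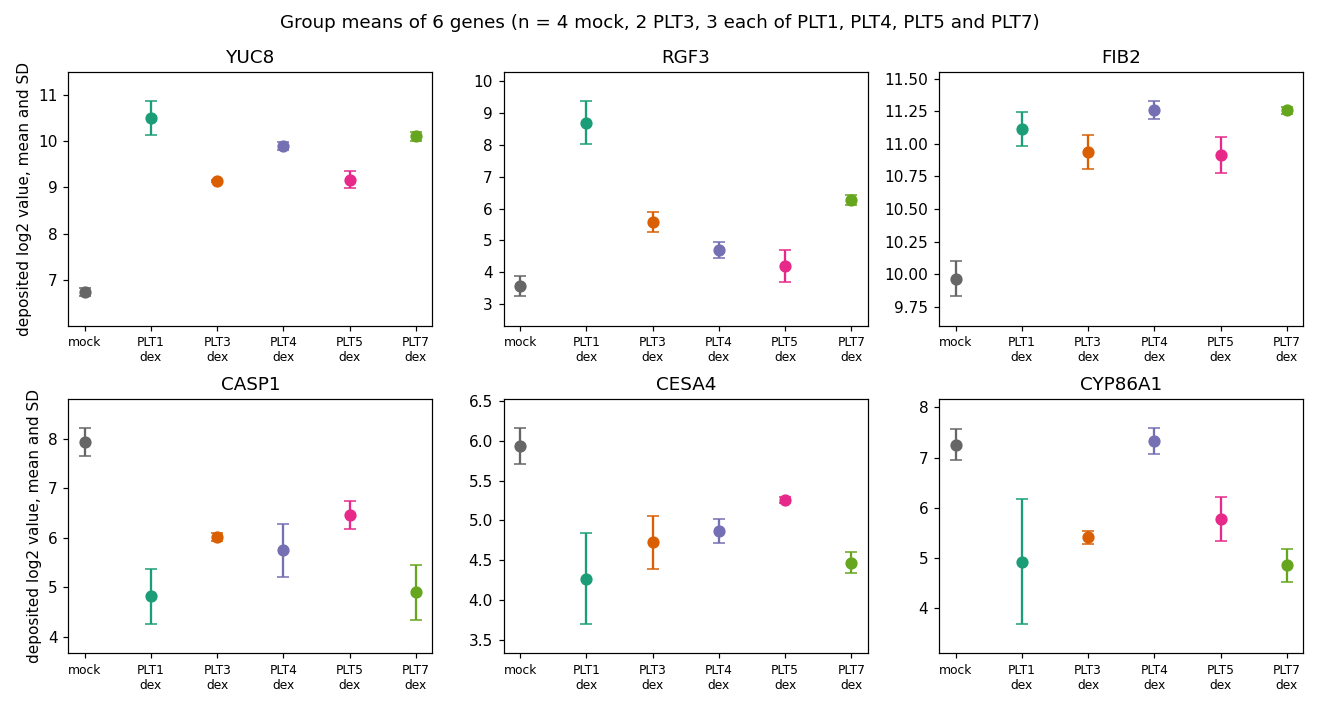
Deposited log2 value (vertical axis, mean with SD) of 6 genes in the mock and dex groups (horizontal axis, n = 4 mock, 2 PLT3 and 3 in each other group, the library labelled PLT1 replicate 3 included). YUC8 went from 6.73 in mock to between 9.13 and 10.49 in the dex groups, and CYP86A1 was 7.25 in mock and 7.33 in PLT4 dex.

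Differences between the induced lines were tested without reference to mock. Each PLT is represented by a single line, which the labels' protocols split into flasks, so the p-values measure the spread within a line. Only the PLT4 line has a mock group. Differences between the lines before induction therefore cannot be told from effects of the induced PLT. Beyond the PLT genes themselves, the strongest differences lay in SYTC, a synaptotagmin, the brassinosteroid-inactivating P450 BAS1, ADF9, the amino acid permease AAP6, GLIP7 and the homeobox gene HB52. The PLT1 averages given here include the library labelled PLT1 replicate 3, which lacked the PLT1 transcript. SYTC averaged 7.24 in PLT1 and 7.49 in PLT7 but 4.73 to 5.07 in the 3 others. AAP6 averaged 5.48 in PLT1 and 6.38 in PLT7 against 8.20 to 8.55 in the 3 others, and HB52 4.1 and 4.34 against 6.37 to 6.47. GLIP7 averaged 4.34 in PLT1 and 4.39 in mock, but 8.11 in PLT3, 7.63 in PLT4, 6.34 in PLT5 and 6.24 in PLT7. The adjusted p of these 6 genes from the F test ran from 2.62e-09 to 4.61e-09. The F test called 5807 probe sets, and 7861 without the library labelled PLT1 replicate 3.

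By pairs, PLT3 and PLT5 differed in 82 probe sets, PLT3 and PLT4 in 166 and PLT4 and PLT5 in 455. PLT1 and PLT5 differed in 5366, PLT5 and PLT7 in 3730, PLT1 and PLT4 in 3305, PLT1 and PLT3 in 3162, PLT4 and PLT7 in 2475, PLT3 and PLT7 in 2122 and PLT1 and PLT7 in 1778. PLT3 has 1 library fewer than the other lines, which lowers its counts. Without the library labelled PLT1 replicate 3 the first 3 counts were 444, 767 and 1541, and the next 7 were 7236, 5099, 5262, 5123, 3896, 3442 and 3477. The SD of the log2 changes over all probe sets, without that library, was 0.785 in PLT1, 0.629 in PLT7, 0.473 in PLT4, 0.456 in PLT3 and 0.366 in PLT5. The jasmonate, touch and wounding list was lower in PLT7 than in PLT4, with 5 of 9 members called (adjusted p = 8.68e-05, or adjusted p = 0.0124 with an estimated correlation) and than in PLT5 with 5 of 9 (adjusted p = 0.000152, or adjusted p = 0.0155 with an estimated correlation).

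The mean of PLT1 and PLT4, known from the root meristem and the embryo, was set against that of PLT5 and PLT7, known from organ positioning and lateral roots. The changes of genes and lists include the library labelled PLT1 replicate 3 in the PLT1 group. Higher in the mean of PLT1 and PLT4 were ADF9 (1.56 ± 0.14), the auxin-synthesis gene YUC3 (1.48 ± 0.23), RGF3 (1.47 ± 0.21), the purine permease PUP4 (1.45 ± 0.23), the glucosyltransferase UGT71B1 (1.37 ± 0.10) and CRF3 (1.24 ± 0.09). Lower were 4 genes of methionine-derived glucosinolate synthesis, AOP2 (-2.07 ± 0.18), BCAT4 (-1.90 ± 0.31), MAM1 (-1.60 ± 0.33) and IMS2 (-1.37 ± 0.32), and NRT1.5 (-1.63 ± 0.38). Of the mitotic genes 5 of 14 were higher, and 6 when adjusted over the list alone (adjusted p = 0.00123, or adjusted p = 0.457 with an estimated correlation), with HIK at 0.53 ± 0.15, whose call ended with any 1 of 10 libraries left out (adjusted p from 0.0509 to 0.085). Of the ribosome biogenesis genes 3 of 9 were higher, and 7 when adjusted over the list alone (adjusted p = 0.000256, or adjusted p = 0.362 with an estimated correlation), with FIB1 at 0.29 ± 0.06. The hypoxia list was called higher, with 2 of 10 members, and 3 when adjusted over the list alone (adjusted p = 0.0078, or adjusted p = 0.362 with an estimated correlation, and 0.277 with dim probe sets left out). The xylem list was called lower, with 1 of 10, and 2 when adjusted over the list alone (adjusted p = 0.00526, or adjusted p = 0.362 with an estimated correlation), and so was the photosynthesis list with 0 of 13, and 3 when adjusted over the list alone (adjusted p = 0.00123, or adjusted p = 0.362 with an estimated correlation). YUC8 was higher by 0.56 ± 0.10. PLT4 averaged below PLT7, however, in ADF9 (8.86 and 9.29), YUC3 (6.69 and 7.88), RGF3 (4.70 and 6.28), PUP4 (3.87 and 4.09) and YUC8 (9.89 and 10.11), and above it in AOP2 (7.41 and 7.19) and MAM1 (8.32 and 8.30), so these differences of means rest on PLT1 or on PLT5. Between PLT4 and PLT7, of these 5 lists the ribosome biogenesis list was called (adjusted p = 0.00234, or adjusted p = 0.437 with an estimated correlation), and the mitotic, photosynthesis, xylem and hypoxia lists were not (adjusted p = 0.966, 0.733, 0.258 and 0.136). The contrast called 1794 probe sets, 949 higher and 845 lower, 3814 without the library labelled PLT1 replicate 3 and 1116 without PLT5 replicate 2. At least 2-fold were 77 of them, 35 higher and 42 lower.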

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

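Of the tests below, all those on the library labelled PLT1 replicate 3, the reading of a close family member by a probe set and the count for PLT4 left out were chosen only after the result was seen, as was the count of splits without PLT5 replicate 2, while the tests of a small RNA share and of the other splits were set before.

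The PLT2 probe set stood at 10.28 in the library labelled PLT1 replicate 3, where the highest of mock and its own group was 4.38. A mixture with RNA of the PLT1 line would keep some PLT1 signal, but its PLT1 value minus the highest of the 15 libraries of other groups was -0.42. A swap inside the series needs a partner with high PLT1, yet the highest PLT1 value of the other groups was 0.24 above the mock mean. Its highest correlation with a mock library was 0.955, below the lowest of the PLT5 libraries, 0.978. This cannot decide whether a line had lost its transgene, because no group received dex without a fusion. The actin difference, which grows as RNA degrades, was also larger in this library than in all others. RNA of a line that drives PLT2 from outside the 5 lines could account for the PLT2 signal, since PLT2 lay 4.21 above all 17 other libraries. A further PLT2 experiment is named in the labels' protocols, its data are not analysed here, and no biological explanation was tested.

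Smaller signals of the same kind were PLT2 at 6.07 in PLT5 replicate 3, against 4.06 for the highest other of its group and mock, and PLT3 at 6.49 in PLT7 replicate 1, against 4.76. Reading of a family member by the probe set would raise all libraries of the group alike, yet these 2 libraries lay 2.01 and 1.86 above the higher of the others of their group. A small share of RNA from another line could account for the PLT2 signal. A share of 4.17% computed from PLT2 predicts a median shift of 0.278 over 103 probe sets. There 0.296 was seen, against -0.127 and -0.188 in the other libraries. For PLT3 a share of 3.52% predicts 0.168 over 21 probe sets, where 0.336 was seen against -0.224 and 0.0481. That shift is in the predicted direction, but larger than the share alone gives. The other libraries are not independent of the 1 with the signal, the PLT2 profile was taken from the doubted library, and no biological explanation was tested.

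Some probe sets were called the same way in 4 lines and differed from the line left out in all 4 pairs. With PLT4 left out there were 47, against 43, 7, 27 and 40 for PLT1, PLT3, PLT5 and PLT7, all without the doubted library. Higher in the 4 other lines were 8 for PLT4, against 18, 5, 13 and 23 for PLT1, PLT3, PLT5 and PLT7. The suberin genes CYP86A1 and GPAT5 were among the 47. A difference between the PLT4 line, which is also the mock, and the other lines before induction might add such probe sets. The counts 47 and 43 lie within counting error, by a margin set after the counts were seen. That error takes probe sets as independent, which they need not be, and the difference in direction was not tested. The cases cannot be told apart, because only the PLT4 line has a mock group, and a response peculiar to PLT4 stays open, untested.

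Other splits of the libraries were counted for results of at least 3 libraries a group. For PLT1, PLT4, PLT5 and PLT7 against mock, 1 of 35 splits, the real one, reached 10361, 7224, 4904 and 9265 calls. The highest others gave 6408, 4126, 1895 and 5380, and 35 splits are too few to exclude chance. Those highest others exchange the line's 3 libraries for 3 of the mock libraries and are near mirrors of the real split. In 100 drawn splits 1, the real one, reached 9736 calls for the mean of the 5 lines, 3445 for all 5 lines, 5807 for the F test and 1794 for PLT1 and PLT4 against PLT5 and PLT7. The highest others were 3631, 0, 2631 and 1745, which left a wide distance for the first 3. For the last the distance was small. These splits exchange single libraries and not whole lines, and splits that mix groups widen the spread within them. They cannot exclude chance differences between lines. Nor can they decide whether another pairing of the lines would give as many calls. Without PLT5 replicate 2, the library whose absence lowers that last count most, 3 of 100 splits, the real one included, reached its 1116 calls, and the highest other gave 1541. The 10 splits of a pair are too few for a share under 0.05. The real values and highest others were 3305 and 171 for PLT1 and PLT4, 5366 and 0 for PLT1 and PLT5, 1778 and 2 for PLT1 and PLT7, 455 and 0 for PLT4 and PLT5, 2475 and 0 for PLT4 and PLT7, and 3730 and 0 for PLT5 and PLT7.

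Among the named genes, 6 had a mock library far from the 3 others: LAX3 at 8.02 in replicate 3 (others 8.24 to 8.27), PLT3 at 4.59 in replicate 1 (4.73 to 4.76), and in replicate 4 ROP9 at 6.10 (5.54 to 5.58), AGL15 at 3.47 (3.70 to 3.74), FIB1 at 11.03 (11.25 to 11.30) and CYP86A1 at 6.80 (7.36 to 7.46). Chance marks about 1 in 20 groups, or 5.4 of the 108 genes looked at. The endogenous PLT5 transcript went in opposite directions in some lines, by -0.38 in PLT1 and -0.49 in PLT7 but 0.49 in both PLT3 and PLT4. Without the library labelled PLT1 replicate 3 the change in PLT1 was -0.25 (adjusted p = 0.168) and not called. The other 3 were not called without 1 library of their own line, PLT3 without replicate 1 (adjusted p = 0.295), PLT4 without replicate 3 (0.0868) and PLT7 without replicate 3 (0.0631). The differences were -0.87 (adjusted p = 0.00241) for PLT1 against PLT3, -0.86 (adjusted p = 0.000943) for PLT1 against PLT4, 0.99 (adjusted p = 0.00139) for PLT3 against PLT7 and 0.98 (adjusted p = 0.00043) for PLT4 against PLT7, from limma.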

How the results depend on the processing

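The fits without PLT1 replicate 3, PLT5 replicate 3 and PLT7 replicate 1 together were chosen only after the data were seen. No called change of a named gene or list turned its direction under the alternatives run. Changes that were not called did, among them CYP86A1 in PLT4 (0.07) without mock replicate 4 (-0.08, adjusted p = 0.921) or PLT4 replicate 1 (-0.07, 0.936) and LEC1 in PLT4 (0.04) without mock replicate 3 (-0.03, 0.873) or PLT4 replicate 2 (-0.01, 0.971). With a 2-fold minimum, which keeps fewer probe sets by construction, the calls were 2385 for PLT1, 876 for PLT3, 1123 for PLT4, 442 for PLT5, 2001 for PLT7, 1227 for the mean of the 5 lines, 77 for PLT1 and PLT4 against PLT5 and PLT7, 4336 over all pairs and 301 for all 5 lines. Array weights, which gave the library labelled PLT1 replicate 3 a weight of 0.138, raised the calls to 3941 for PLT1 and PLT4 against PLT5 and PLT7, 39113 over all pairs (22641 without weights) and 8880 in the F test. With those 3 libraries left out, PLT1 and PLT4 against PLT5 and PLT7 gave 2701. The fall of PLT4 in its own line passed with array weights (-0.69, adjusted p = 0.000778), with only the compared groups (-0.72, adjusted p = 9.16e-05) and with those 3 libraries left out (-0.72, adjusted p = 7.26e-06), in each of which the doubted library counts less or not at all. The order of the lines by calls also turned: PLT7 had more than PLT1 with array weights (10292 and 9877) and with only the compared groups (9430 and 7830), where PLT3 had fewer than PLT5 (5112 and 5216), as it did without either PLT3 library (3212 or 3303 against 4652). The balance of directions was turned by the 2-fold minimum, with higher and lower calls of 1012 and 1373 for PLT1 (5443 and 4918 without a minimum), 336 and 540 for PLT3 (2771 and 2705), 518 and 605 for PLT4 (3758 and 3466), 779 and 1222 for PLT7 (4860 and 4405), 465 and 762 for the mean of the 5 lines (4922 and 4814), 35 and 42 for PLT1 and PLT4 against PLT5 and PLT7 (949 and 845) and 149 and 152 for all 5 lines (1866 and 1579), and PLT5 had 221 each (2418 and 2486). It also turned for PLT1 and PLT4 against PLT5 and PLT7 after median centring (848 and 930), after quantile normalisation (876 and 969) and without PLT4 replicate 1 (621 and 623), and for PLT3 with only the compared groups (2552 and 2560) and without mock replicate 4 (2556 and 2565). For PLT5 it turned after median centring (2742 and 2110), after quantile normalisation (2563 and 2356), with dim probe sets left out (2287 and 1706), with those 3 libraries left out (2469 and 2421) and without any 1 of mock replicates 1, 2 and 3 and the 3 PLT5 libraries. Beyond these the cause was not tested.

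Leaving out each library in turn, the lowest and highest calls were 9593 and 10883 for PLT1, 3212 and 6779 for PLT3, 5869 and 8468 for PLT4, 3274 and 6283 for PLT5, 8117 and 10189 for PLT7, 8921 and 10735 for the mean of the 5 lines, 1116 and 3814 for PLT1 and PLT4 against PLT5 and PLT7, 18232 and 36287 over all pairs, 2389 (without PLT3 replicate 1) and 4325 for all 5 lines, and 4729 and 7861 in the F test, each highest without the library labelled PLT1 replicate 3. The induced genes ranged from 3.57 to 7.36 for PLT1, 6.16 to 6.25 for PLT3, -0.75 to -0.67 for PLT4, 4.75 to 4.89 for PLT5 and 7.42 to 7.53 for PLT7. Of the list tests, 58 calls were lost with an estimated correlation and 5 with quantile normalisation, among the latter photosynthesis in PLT3 (adjusted p = 0.207), PLT4 (0.054) and PLT7 (0.0883). With dim probe sets left out 11 were gained and 8 lost. Values near background compress changes, which limits what dim probe sets show.

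The replicate numbers did not pair the libraries: of 40 pairs with the same number 3 correlated above 0.1, from -0.162 to 0.236, and 8 of 18 libraries correlated best with their own number. With the replicate block the calls were 9785, 4732, 6662, 4333 and 8835 for PLT1, PLT3, PLT4, PLT5 and PLT7, 8836 for the mean of the 5 lines, 1861 for PLT1 and PLT4 against PLT5 and PLT7, 22977 over all pairs, 3006 for all 5 lines and 5804 in the F test, and 4 list calls were not made: cytokinin in PLT1 (adjusted p = 0.067), root stem cell niche in PLT3 (0.0605) and seed storage in PLT3 (0.119) and PLT4 (0.0701). PLT3 then had 2358 higher and 2374 lower, and CYP86A1 in PLT4, not called, was at -0.08.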

Other observations

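The tests of gene families in this part were chosen only after the largest changes were seen, and their members carry some of those changes. The list of aliphatic glucosinolate synthesis was called lower in the mean of the 5 lines, with 13 of 16 measured members lower and 1 higher, a median change of -1.13 and adjusted p = 5.92e-06 from camera, or adjusted p = 0.0622 with an estimated correlation. Without the members already named for their size, 9 of 12 were lower (adjusted p = 0.000186, or adjusted p = 0.0646 with an estimated correlation). The median was -2.35 in PLT1 and -0.32 in PLT5, where the list was not called (adjusted p = 0.0824), though it was without the library labelled PLT1 replicate 3 (adjusted p = 0.0229, or adjusted p = 0.338 with an estimated correlation).

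Of the PIP and TIP aquaporins 14 of 19 were lower and 1 higher, with a median change of -1.15 (adjusted p = 2.79e-07, or adjusted p = 0.0473 with an estimated correlation, and 0.0508 without the library labelled PLT1 replicate 3). Without the member already named for its size, 13 of 18 were lower (adjusted p = 8.41e-07, or adjusted p = 0.048 with an estimated correlation, and 0.0621 without that library too). The aquaporin list was drawn by current symbol alone and was not completed, so its counts need not hold for the whole family. Of the xyloglucan-modifying XTH enzymes 16 of 30 were lower and 4 higher (adjusted p = 0.000277, or adjusted p = 0.0146 with an estimated correlation), and without the 2 named members 14 of 28 were lower (adjusted p = 0.00194, or adjusted p = 0.0371 with an estimated correlation). In PLT5 the XTH list was not called (adjusted p = 0.0824, and 0.181 without the named members), though it was without the library labelled PLT1 replicate 3 (adjusted p = 0.0356, or adjusted p = 0.162 with an estimated correlation, and 0.143 without the named members). The alpha-expansins, 8 of 20 lower and 4 higher, were not called (adjusted p = 0.162).

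The XTH and alpha-expansin lists were also drawn by current symbol. This leaves out 3 measured XTH genes, TCH4 among them, and 1 alpha-expansin that are filed under older names. These 2 lists were tested again with those genes only after the values above were seen. Of the XTH genes 19 of 33 were then lower in the mean of the 5 lines (adjusted p = 3.62e-05, or adjusted p = 0.00367 with an estimated correlation). In PLT5 13 of 33 were lower, and the list passed (adjusted p = 0.038) but not with an estimated correlation (adjusted p = 0.125) or without the 2 named members (adjusted p = 0.0829). Of the alpha-expansins 9 of 21 were lower and 4 higher, and the list was not called (adjusted p = 0.106). It was without the library labelled PLT1 replicate 3 (adjusted p = 0.0286, or adjusted p = 0.126 with an estimated correlation), which the list by current symbol was not (adjusted p = 0.077).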
